A study of Mus musculus with 6 samples.

How the data were processed

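RNA from mouse forelimb buds at E10.5, dissected into a proximal and a distal part, was measured on 6 one-colour Affymetrix arrays. Per the labels, total RNA was extracted with RNeasy Micro columns and biotin-labelled cRNA was made by in vitro transcription. The deposited values are signal intensity from the authors' MAS5 processing, on a linear scale, with each array scaled so that its mean signal is 500 after the lowest and highest 2% of probe sets are left out. The MAS5 version is not given in the sources used here, and the table holds no detection calls. No column of per-sample values was left out. The number of arrays limits the precision: each of the 6 combinations of part and condition has 1 array.

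The conditions were taken from the labels. The control is described as wild type but carries the genotype label Ring1A-/-, and the series design names it as the Ring1A knockout. The dKO is Prx1-Cre;Ring1A-/-;Ring1Bfl/fl, so by the genotype labels it differs from the control in Ring1B and the Cre transgene. The RA arrays are from wild type embryos exposed to all-trans retinoic acid (RA), 100 mg/kg by maternal gavage at E10.25. RA exposure and the Ring1A genotype label therefore change together in every comparison of RA with control.

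The table has 45101 probe sets, of which 64 are controls. The annotation lists 35890 of them, 34958 with 1 gene symbol and 932 with several, and 9211 have no listed gene. For 34754 of the single-symbol probe sets the gene ID matched the RefSeq table, and 0 symbols changed by that match. Each of 18193 genes was represented by the probe set with the highest mean log2 signal over the 6 arrays. Signals below the median of their array were set to that median, called the floor, before log2 was taken. A gene entered a comparison of arrays when at least 1 of the arrays was above its floor. A fold against a floored value is a lower bound and is given as "at least"; a negative log2 value that ends at a floored array is called a bound. Differences between single arrays have no replicate check and no p-value. Genes were counted at 2-fold or more, and overlaps of counts were set beside the number expected from independent lists.

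An additive model with condition and part as terms was fitted to the 12147 genes above the floor on at least 1 array, with limma 3.58.1 (trended prior variance, Benjamini-Hochberg adjustment, adjusted p under 0.05). It has 2 residual degrees of freedom, and the variance pooled over genes enters with 4.64, so its p-values rest mostly on that pooled variance. Fits without a pair of arrays have 1, so their p-values rest on it even more. The residual is the disagreement of an effect between pairs of arrays, so the fit asks whether an effect is alike across pairs and is not a replicate test. For a gene at the floor on several arrays, the values there are only the array floors. Part of the agreement between pairs is then set by the floors, which can make the p-value of such a gene too small. "Rose", "fell" and "changed" below are used for genes past that threshold, and "higher" and "lower" for differences between single arrays. The fit was tested on simulated data in which 200 genes were changed: it recovered 95% of 2-fold and 100% of 4-fold changes, called 201 genes, and 2.99% of its calls were false. In simulated arrays with 100 genes changed 3-fold each way, the count of genes 2-fold in both parts recovered 100% of them with 0 false calls. The first simulation drew independent noise of the same per-gene spread on every array, with no disagreement between parts and no outlying array. The second used copies of 1 array with small noise and changed only bright genes. Both check the computation and give no error rate for the real arrays.

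The following choices were made before the data were examined: the floor, the thresholds, the comparisons, 30 gene lists and the rule for naming genes. The lists are PRC1 and PRC2 components, proximal limb genes, distal limb genes, FGF response genes, apical ectodermal ridge genes, SHH pathway and posterior genes, anterior limb genes, RA response genes, RA synthesis genes, the HoxA, HoxB, HoxC and HoxD clusters, non-limb developmental regulators that are typical Polycomb targets, Cdkn2 locus and p53 target genes, proliferation genes, chondrogenic genes, BMP pathway genes, WNT pathway genes, limb mesenchyme genes and hindlimb genes, markers of surface ectoderm, muscle precursors, endothelium, erythroid cells, macrophages, neural and Schwann cells, somite and body wall, and mesothelium, and sex-linked genes. Some genes are on more than 1 list, among them Irx3, Irx5, Meis1, Meis2, Cyp26b1, Isl1, Hoxc10, Pax1, Pax9, Tbx18, Wt1, Wnt6 and Hoxb1. For each list the median log2 difference was placed among the medians of 10000 random lists of the same size, matched on mean signal in 20 bins (seed 1). The limma p-values of a list's members were also adjusted over the list alone. No adjustment was made across the 30 lists or the effects, and lists share members. The counts adjusted over the list alone therefore have no common error rate.

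Genes are named by this rule. Ring1, Rnf2, Meis1 and Meis2 are named whatever their values. For each effect, the 10 genes with the largest mean log2 difference each way are named among those 2-fold or more the same way in every pair and above the floor on both sides, and up to 5 genes each way whose dim side lies at the floor. For dKO and for RA, the 4 genes each way with the largest difference between the parts are named, and up to 6 genes each way that are 2-fold in both parts under both conditions. From each list, up to 6 members 2-fold or more are named, and members said not to have changed. Genes outside this rule are said to have been chosen after their values were seen.

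Because dKO and RA are compared with the same control array within a part, their correlation across genes was set beside 100 simulations without any effect, drawn with normal noise of the same per-gene spread on every array, the shared control included. That spread was taken by signal bin from the disagreement of the dKO effect between parts, which can hold real differences as well as noise. After the data were seen, genes 2-fold in both conditions were set beside 1000 simulations in which the dKO and the RA differences were shuffled apart among genes of like signal, without and with such noise. The shuffled differences already hold the noise of their arrays, so the version with added noise holds too much and raises the simulated counts. Lists were then also read over all members on the array and over members above the floor in control. Position differences in the dKO and RA pairs were also compared with the control pair on genes chosen on the pair that was not compared. Alternatives were quantile normalization, division of each array by its median, floors at the 30th and 70th percentile, an offset in place of a floor, the mean over all probe sets of a gene, leaving out probe sets that can bind several transcripts, a 3-fold threshold, fits with no filter or no trend, and fits without each pair. Left out were control probe sets, probe sets that name several genes and, outside the closing section, probe sets without a listed gene. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3 were used.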

Results

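Transcript levels were measured in mouse forelimb buds at E10.5, when the limb is an outgrowth of mesenchyme covered by ectoderm. Each bud was divided into a proximal and a distal part, and 1 array was made for each part in each of 3 conditions: control, combined loss of Ring1A and Ring1B (dKO), and RA exposure. RING1A and RING1B are the E3 ubiquitin ligases of Polycomb repressive complex 1, and RA is a signalling molecule active in the body wall and proximal limb. With 1 array per group, none of the differences between arrays has a replicate check. Median signals, used as floors, were 64.0 in the proximal and 59.5 in the distal control array, 73.0 and 76.1 in the dKO arrays and 63.0 and 68.2 in the RA arrays. The numbers of genes above the floor were 11043, 11144, 11376, 11360, 11134 and 10888 in the same order.

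The RA arrays differed from the other 4 in features unrelated to limb patterning. Xist, the RNA that coats the inactive X chromosome, had signals of 3017 to 3688 on the control and dKO arrays and 12.9 and 29.5 on the RA arrays. Eif2s3y, a Y-linked gene, had signals of 2783 and 3064 on the RA arrays and at most 12.3 on the others. Of the sex-linked list, 1 gene was higher and 1 lower in RA in both parts, and in limma 1 rose and 1 fell over all genes as well as adjusted over the list alone. The BioB spike-in had a signal of 153 and 146 on the RA arrays and 1246 to 1364 on the others. The other spike-ins differed far less. BioC was 2128 and 2208 on the RA arrays (others 2440 to 2645) and BioD 6221 and 7238 (others 6673 to 7580). Cre was 16167 and 14827 (others 13261 to 14693). The proximal RA array correlated with the others at r = 0.912 to 0.934 across genes, against 0.984 between the control arrays and 0.985 between the dKO arrays; genes are not independent replicates. Its 3'/5' ratios were the highest, 1.60 for GAPDH (others 1.28 to 1.39) and 1.95 for actin (others 1.52 to 1.72), as were its GAPDH 3' signal of 17338 (others 9785 to 11383) and its maximum of 26458 (others at most 16620).

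The first question is how the targeted genes and the Meis genes, which encode homeodomain factors of the proximal limb, appear in each condition. Ring1, which encodes RING1A, had signals of 624 proximally and 968 distally in control, 402 and 578 in dKO, and 419.8 and 245 in RA. Ring1 signal was thus no lower in the control, labelled Ring1A-/-, than in the RA arrays, labelled wild type. Rnf2, which encodes RING1B, had signals of 2042 and 2070 in control, 2147 and 1887 in dKO, and 1941 and 2085 in RA. Where the probes lie relative to the deleted exons is not given in the sources used here, so neither gene checks the deletion. Meis2 had signals of 2941 and 1094 in control, 3456 and 2235 in dKO, and 4890.1 and 3411 in RA. In the distal part, Meis2 was higher in dKO (log2 1.03) and in RA (log2 1.64), against 0.23 and 0.73 proximally. In limma neither effect on Meis2 passed the threshold (dKO log2 0.63, adjusted p = 0.346; RA log2 1.19, SE 0.23, adjusted p = 0.0915). Meis1 had signals of 614 and 202 in control, 709 and 582 in dKO, and 375 and 397 in RA; its distal log2 difference was 1.53 in dKO and 0.98 in RA.

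**Figure D1:**
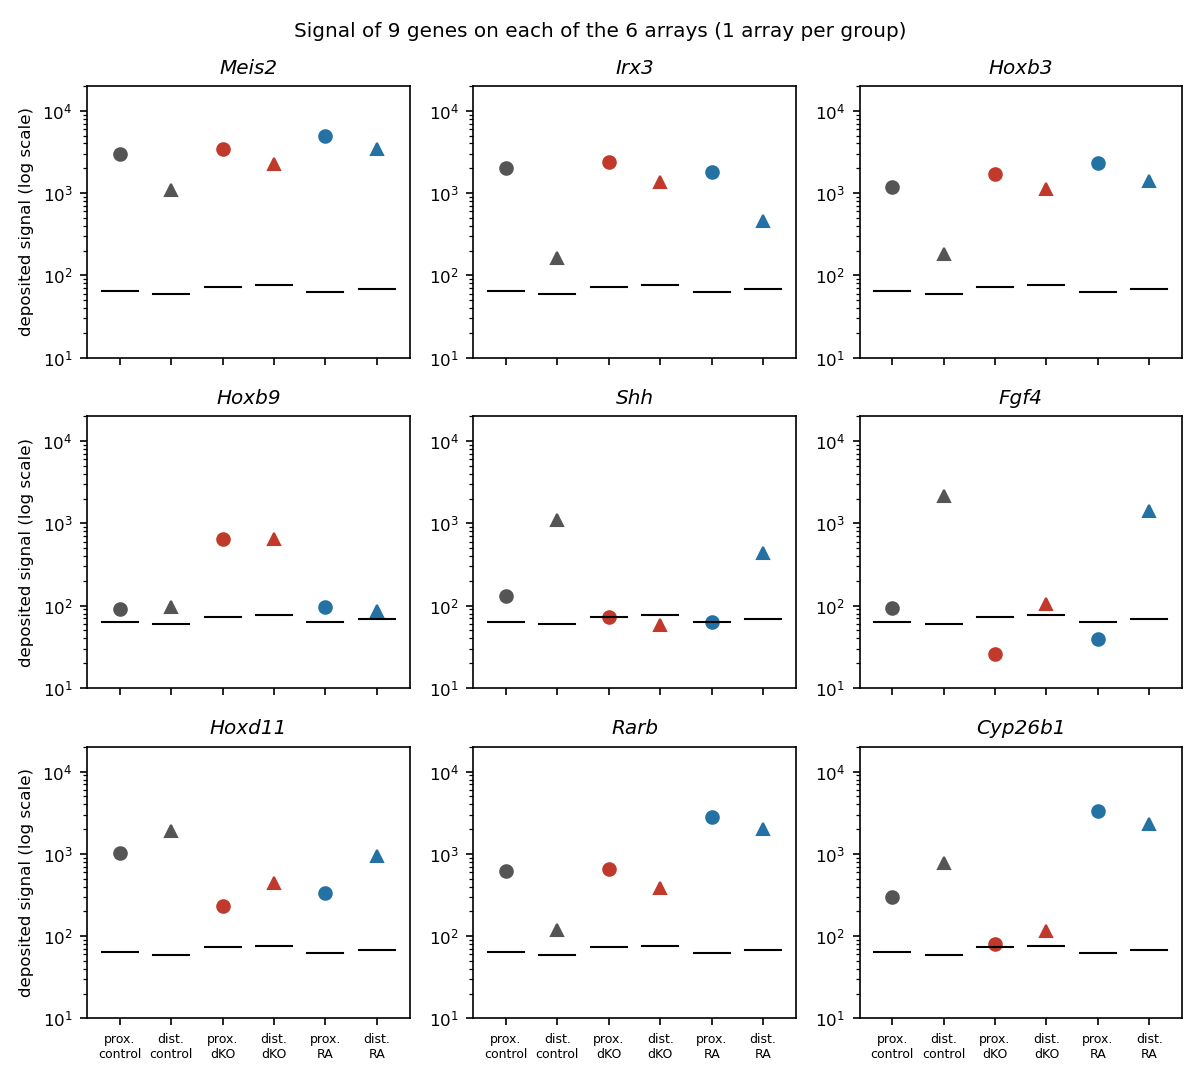
Deposited signal (log axis) of 9 genes on each of the 6 arrays. Circles are proximal and triangles distal arrays; grey is control, red dKO and blue RA, and the black line is the floor of each array. Irx3 has signals of 2018 proximally and 160.4 distally in control, and 2369.6 and 1367 in dKO.

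The control pair answers which transcripts separate the proximal from the distal bud. Proximal limb genes were higher proximally: 5 of 10 measured members were 2-fold or more higher and 0 lower, with a median log2 difference of 1.10. Irx3, an Iroquois homeobox gene, differed by 3.65, and its neighbour Irx5 by at least 2.08. The HoxB cluster had 4 of 7 members higher proximally and 0 lower (median 1.96), with Hoxb5 at 2.91, Hoxb3 at 2.72, Hoxb6 at least 2.33 and Hoxb4 at 1.96. All 4 measured anterior limb genes were higher proximally (median 2.69), Pax1 by at least 3.31 and Alx1 by 1.55. The others were Irx3 and Irx5, counted already among the proximal limb genes, and Pax1 is also on the somite and body wall list. This list is therefore not a separate result. Genes of the apical ectodermal ridge, the distal signalling epithelium, went the other way: 6 of 11 were lower proximally and 0 higher, with a median of -1.28. Fgf4, a ridge growth factor, had a signal of 2141 distally and 92.7 proximally (log2 -4.53), and Fgf8 (-1.90, a bound), Dlx5 (-1.94, a bound) and Sp8 (-1.36) were also lower. Each of these medians lay beyond those of all 10000 random lists.

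Among distal limb genes 4 of 14 were lower proximally and 0 higher (median -0.33), with Hoxd13 at -1.69 and Cyp26b1, an RA-degrading enzyme, at -1.37. Of the SHH pathway and posterior genes, 3 of 9 were lower and 0 higher (median -0.54): Shh, the posterior signal (-3.08), Grem1 (-1.76) and Gli1 (-1.27). FGF response genes had 1 of 9 lower, Spry1 (-1.19), and a median of -0.42. These 3 medians were below those of all random lists. The HoxA, HoxC and HoxD clusters had 2 of 8, 2 of 6 and 1 of 7 members higher and 0, 2 and 1 lower, with Hoxc4 (2.13) and Hoxc8 (-1.39) as examples in HoxC.

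Markers of other tissues moved along with these groups. Muscle precursor markers were higher proximally in 2 of 4 (Lbx1 2.58, Pax3 2.33) and somite and body wall markers in 5 of 7, Tcf15 by 1.24. Surface ectoderm markers were lower proximally in 2 of 12, Krt5 (-1.91) and Epcam (-1.19), with a median of -0.79 below all random lists, as for the ridge genes, which are ectodermal themselves. The BMP list had 1 of 10 higher and 2 lower, and the WNT list 2 of 16 higher and 3 lower, with Bmp2 (-2.37) and Sfrp1 (2.36) as the largest. Of the Cdkn2 locus and p53 target genes, 2 of 11 were lower, Cdkn1a (-1.89) and Pmaip1 (-1.32). Endothelial markers were higher proximally in every pair by their medians (0.26 in control, 0.48 in dKO and 0.63 in RA, at percentiles 99.1, 99.98 and 99.6 of random lists), with 3 of 10 at 2-fold in RA alone, and 3 were higher adjusted over the list alone. After division by the array median 4 ectoderm markers were lower in control.

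In all, 154 of 11391 genes were higher proximally and 159 distally in control. In all 3 pairs 24 genes were higher proximally and 21 distally. Fap, a serine protease of mesenchymal cells, was higher proximally by 3.28 in control, 2.61 in dKO and 4.64 in RA. Lbx1, a homeobox gene of migrating muscle precursors, was higher by 2.58, 2.24 and 4.53, and Sned1 by 2.55, 1.16 and 3.13. Also higher proximally were Nav3, Mn1, Runx1t1, Synpo, Ak1, Rnf182 and Olfml3. Higher distally in all pairs were Tent5a (-2.95, -1.36 and -2.91), Wnt7a, a dorsal ectoderm signal (-1.84, -1.59 and -1.74), Ccdc3, Dmrta1, Sct, Vax2, Prap1, Nap1l5, Ripk4 and Bhlha9. Cntn2 was at the floor proximally in every pair and differed by bounds of -2.48, -1.59 and -2.24.

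The limma fit called 0 genes for position among 12147, with 1156 at an unadjusted p under 0.05. Leaving out a pair changed that count: 124 genes higher and 173 lower proximally without the control pair, 175 and 179 without the dKO pair, and 205 and 226 without the RA pair. These fits have 1 residual degree of freedom and rest even more on the variance pooled over genes. The larger counts are therefore not better supported. Adjusted over the list alone, 9 of 12 ridge genes, 9 of 13 ectoderm markers, 7 of 9 FGF response genes, 5 of 10 SHH genes and 4 of 14 distal limb genes were lower proximally, against 0 over all genes. In the same way 6 of 8 HoxB genes, 4 of 10 proximal limb genes, 4 of 5 anterior genes, 3 of 6 muscle and 3 of 8 somite markers were higher. Of the mixed lists, 3 of 8 HoxA, 2 of 7 HoxC, 1 of 8 HoxD, 2 of 10 BMP and 1 of 16 WNT genes were higher and 1, 1, 2, 3 and 5 lower, and 3 of 12 Cdkn2 and p53 genes were lower. Dividing each array by its median moved the median difference of all genes in control by -0.10 and the counts to 124 higher and 196 lower.

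**Figure D2:**
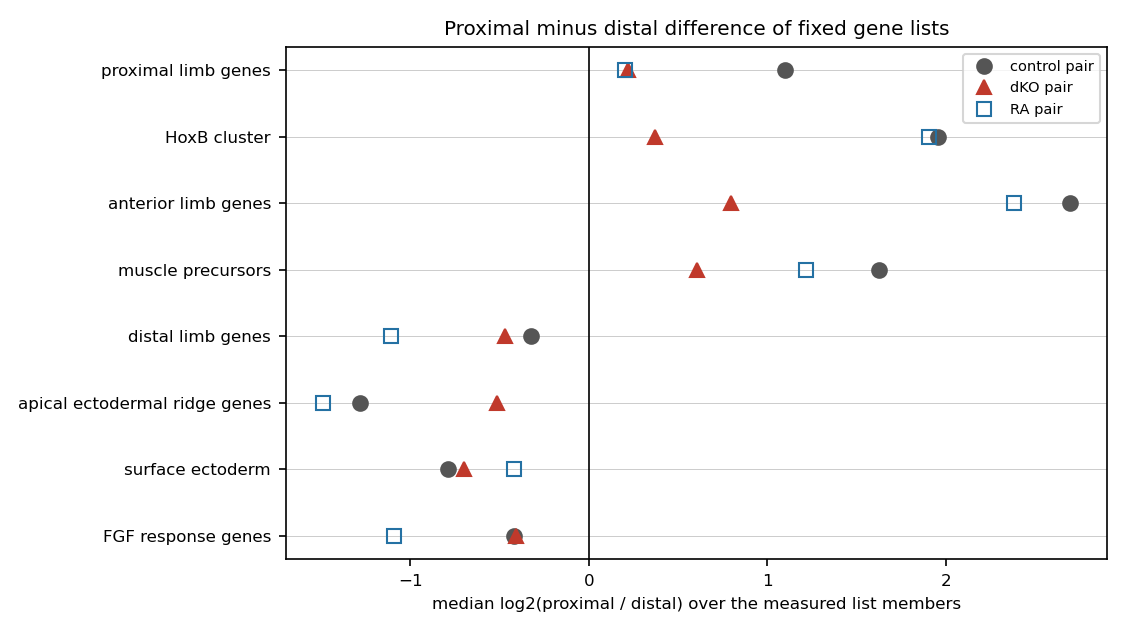
Median log2 ratio of proximal over distal signal for 8 gene lists in the control (grey circle), dKO (red triangle) and RA (blue open square) pairs. The proximal limb list lies at 1.10 in control, 0.22 in dKO and 0.21 in RA, and the ridge list at -1.28, -0.52 and -1.49.

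The comparison of dKO with control asks which transcripts differ between 2 conditions that, by their genotype labels, are both Ring1A-/- and differ in Ring1B. Regulators of other organs were higher: of the non-limb Polycomb targets, 15 of 29 measured were 2-fold or more higher proximally and 18 of 26 distally, and 0 were lower in either part. Of the 60 members on the array, 9 and 10 were above the floor in control, and only these could be lower: 2 and 6 of them were higher, with medians of 0.70 and 1.20. Over all 60, random lists matched on signal had a median of 4 higher members in each part and at most 12 and 13. The medians of the measured members, 1.01 and 1.17, lay above those of all 10000 random lists. After quantile normalization 11 and 10 were higher (0.84 and 0.90), and after division by the array median 11 and 10 (0.82 and 0.81), with 0 lower. In limma 10 rose over all genes and 21 of 32 adjusted over the list alone. Pax6, a regulator of eye and brain, rose from below the floor by at least 2.49 proximally and 2.27 distally, Isl1 by at least 2.25 and 2.03, and Tbx1 by at least 1.75 and 1.07. Gata2, a blood regulator above the floor in control, rose by 1.52 and 1.91.

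Members of the HoxB and HoxC clusters were also higher. Hoxb9 rose from signals of 90.5 and 97.4 to 644 and 646 (log2 2.83 and 2.73; limma adjusted p = 0.0055, SE 0.22), and Hoxb13 rose by at least 1.93 and 1.62. In the HoxC cluster 3 of 7 were higher proximally and 6 distally (medians 0.87 and 1.37), Hoxc10 by at least 3.09 and by 2.96, Hoxc9 by 2.83 and 1.87, and Hoxc8 by 2.11 and 1.15. Hoxc5 was lower proximally (-1.05). In limma 4 of 7 HoxC genes rose over all genes and 5 adjusted over the list alone. The HoxB cluster had 2 of 8 higher proximally and 7 distally, with medians of 0.49 and 1.76. Hoxb3 (2.64), Hoxb6 (at least 2.43), Hoxb5 (1.90) and Hoxb4 (1.56) differed distally, and proximally by 0.52, 0.51, -0.45 and -0.13. In limma 2 HoxB genes rose over all genes and 4 adjusted over the list alone. The HoxD cluster had 2 of 7 higher and 1 lower proximally, and 1 of 8 each way distally: Hoxd1 rose by at least 1.53 and 1.66, and Hoxd11 fell (-2.15 and -2.10). In HoxA 0 of 8 were 2-fold proximally and 1 was higher and 1 lower distally, with 0 calls over all genes and 3 adjusted over the list alone, 1 of them higher. Hindlimb genes, among them Isl1 and Hoxc10, were higher in 2 of 4 proximally and 3 distally. In limma 2 rose over all genes and 4 adjusted over the list alone. Only 0 and 2 of these 4 genes were above the floor in control, with 1 of them higher distally. Random lists matched on signal reached 4 higher members in each part, so these counts do not set the list apart.

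In the distal part, proximal and anterior limb genes were higher in dKO. Proximal limb genes were higher there in 5 of 10 and lower in 1 (median 0.80), and after division by the array median in 3 and 2 (0.45): Irx3 by 3.09, Meis3 by at least 1.55, Meis1 by 1.53, Irx5 by at least 1.27 and Meis2 by 1.03. In the proximal part 1 was higher and 3 lower. Shox2, a gene for the growth of the upper limb segment, fell (-1.11 and -1.08), as did Tbx15 (-1.17 and -0.75). In limma these 2 fell over all genes, and adjusted over the list alone 1 was higher and 2 lower. Anterior limb genes were higher distally in 4 of 5, Alx1 by 1.96 and Pax9 by at least 2.23. In limma 1 rose over all genes and 3 adjusted over the list alone. The others of the 4 were Irx3 and Irx5, counted already among the proximal limb genes, and Pax9 is also on the somite and body wall list.

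Some distal and posterior genes were lower in dKO. Shh had a distal signal of 57.6 in dKO against 1099 in control (-3.85, a bound), and Fgf4 104 against 2141 (-4.36). SHH pathway and posterior genes were lower in 1 of 9 proximally and 3 distally (medians -0.42 and -0.79), Gli1 by -1.06 and -1.72 and Grem1 by -1.71 distally. In limma 0 of 10 changed over all genes and 3 were lower adjusted over the list alone, and after division by the array median 5 were 2-fold lower distally. Ridge genes had 1 of 10 higher and 0 lower proximally (Dlx5, at least 1.28; median 0.30) and 3 of 11 lower distally (-0.34), and none was called in limma over all genes or adjusted over the list alone. Distal limb genes were higher in 1 of 13 (Hoxd13, 1.02) and lower in 2 proximally, and lower in 4 of 14 distally, with medians of -0.41 and -0.32. Cyp26b1 fell (-1.93 and -2.74; limma adjusted p = 0.0484), and with Hoxd11 made 2 of 14 over all genes and 3 adjusted over the list alone. FGF response genes were lower in 1 of 9 in each part, Spry1 (-1.14 and -1.19), which was the 1 gene past the threshold adjusted over the list alone, and had medians of -0.36 and -0.47. The medians of the distal limb and FGF lists lay below those of all random lists in both parts.

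Of the transcripts of PRC1 and PRC2 components, 0 of 24 were 2-fold in either part, and 1 rose in limma over all genes and adjusted over the list alone: Bmi1, a PRC1 subunit (0.95 and 0.86, adjusted p = 0.0331), named after its values were seen. The Cdkn2 locus and p53 targets had 0 of 12 and proliferation genes 0 of 15 at 2-fold in either part, with none called either way; Cdkn2a was at the floor in control and higher distally by at least 0.94. Among chondrogenic genes Acan, a cartilage proteoglycan, rose by at least 1.96 and 2.46 and Runx3 by at least 1.10 and 1.83. These were the 2 of 9 and 2 of 10 list members at 2-fold, and 2 of 10 over all genes and 3 adjusted over the list alone. Of the 7 and 8 members above the floor in control, 0 were higher. Random lists matched to all 13 members on the array reached 4 and 5 higher. Rbp4, a retinol carrier in the RA synthesis list, rose by 1.77 and 1.86, the 1 call of 5 genes both over all genes and adjusted over the list alone, and Aldh1a2, an RA-synthesizing enzyme, was higher proximally by at least 1.998, 2 of 5 measured genes of that list at 2-fold proximally and 1 of 4 distally. The RA response list had 1 of 13 higher and 1 lower proximally and 4 higher and 1 lower distally (2 and 1 after division by the array median), with Rarb higher by 1.70 distally; 1 fell over all genes, and adjusted over the list alone 1 was higher and 1 lower. Limb mesenchyme genes had 0 and 1 of 12 higher and 0 lower, with none called and medians of 0.03 and -0.18, the latter at percentile 0.430.

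Markers of other tissues were read in the same arrays. Neural markers were higher in 1 and 2 of 5, where Nefl, a neurofilament, rose by 1.69 and 2.41, and mesothelium markers in 2 of 3 in each part. After division by the array median the distal counts were 1 and 0, and the distal neural median turned from 0.25 to -0.11. In limma 1 neural and 0 mesothelium markers rose over all genes, and 2 of each adjusted over the list alone. Only 1 and 2 of the 6 mesothelium markers on the array were above the floor in control, with 0 and 1 of these higher. Random lists matched to all 6 reached 3 higher members in each part. Muscle markers were higher in 1 of 6 and 3 of 5, Pax7 by at least 1.82 and 1.49. In limma 0 passed over all genes and 2 adjusted over the list alone. Of those above the floor in control, 0 of 4 and 2 of 3 were higher. Somite and body wall markers were higher in 2 of 8 and lower in 3 proximally (median -0.21), and higher in 2 and lower in 1 distally (0.68). In limma 1 rose and 1 fell over all genes, Pax9 and Meox2, and 2 were higher and 1 lower adjusted over the list alone. Endothelial markers had medians of 0.54 and 0.45, with Erg (1.04) the 1 of 10 at 2-fold proximally and none called in limma. Erythroid cell markers (0 of 7), surface ectoderm markers (0 of 12) and macrophage markers (0 of 5) had none at 2-fold in either part, and limma called none of them. The erythroid medians were 0.38 and 0.21, at percentiles 99.96 and 99.2 of random lists, and the distal one was -0.14 after division by the array median.

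Across all genes, 471 were higher and 42 lower proximally (11580 tested), and 620 higher and 61 lower distally (11646 tested). In 160 and 208 of those higher, control was at the floor. Both parts shared 333 higher genes and 21 lower, where independent lists would share 24.7 and 0.196. This overlap is not replication, since a difference between embryos or batches could appear in both parts. Among genes above the floor in control, Fabp3, a fatty acid binding protein, had the largest rise (3.50 and 3.96). It was followed by Pou3f3, a neural transcription factor (3.18 and 3.24), Galnt12 (2.68 and 2.91), Hoxb9, Kdelr3, Eno2, Chdh, Tcfl5, Ptx3 and Emilin3. From the floor, Zic1, a neural and somite factor, rose by at least 4.55 and 5.12, Ina by at least 3.31 and 3.72, Foxl2os by at least 3.36 and 3.62, Trank1 by at least 3.43 and 3.14 and Cgas by at least 2.94 and 3.42. Mab21l2 fell from 1363 and 1808 to 174 and 247 (-2.97 and -2.87), and Saa1 (-2.14 and -2.58), Mid1 (-2.54 and -2.16), Cdkal1 (-1.87 and -1.42) and Meox2 (-1.04 and -1.72) fell too. H1f2 (-1.43 and -1.34) and Rasgef1b (-1.02 and -1.70) were lower without passing the limma threshold. The largest differences between the parts were in Rcsd1 (1.14 and -1.55), Hoxd13 (1.02 and -0.99), Ppbp (1.14 and -0.51) and Bmp2 (1.54 and -0.10) one way, and in Mup10 (-1.18 and 2.36), Irx3, Prl8a2 (-0.64 and 1.99) and Hoxb5 the other; these differences were not tested.

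In limma 269 genes rose and 14 fell, out of 12147. Of the 333 genes higher in both parts, 92 were at the floor on both control arrays. For these the floors set part of the agreement that the fit rests on. Without the RA pair 1236 rose and 211 fell. That fit has 1 residual degree of freedom and rests even more on the variance pooled over genes. Those larger counts are therefore not better supported. After quantile normalization 80 rose and 7 fell. Dividing each array by its median moved the median of all genes by -0.19 proximally and -0.36 distally, and the distal counts to 321 higher and 192 lower, 62.6% higher against 91.0% with the deposited scaling.

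**Figure D3:**
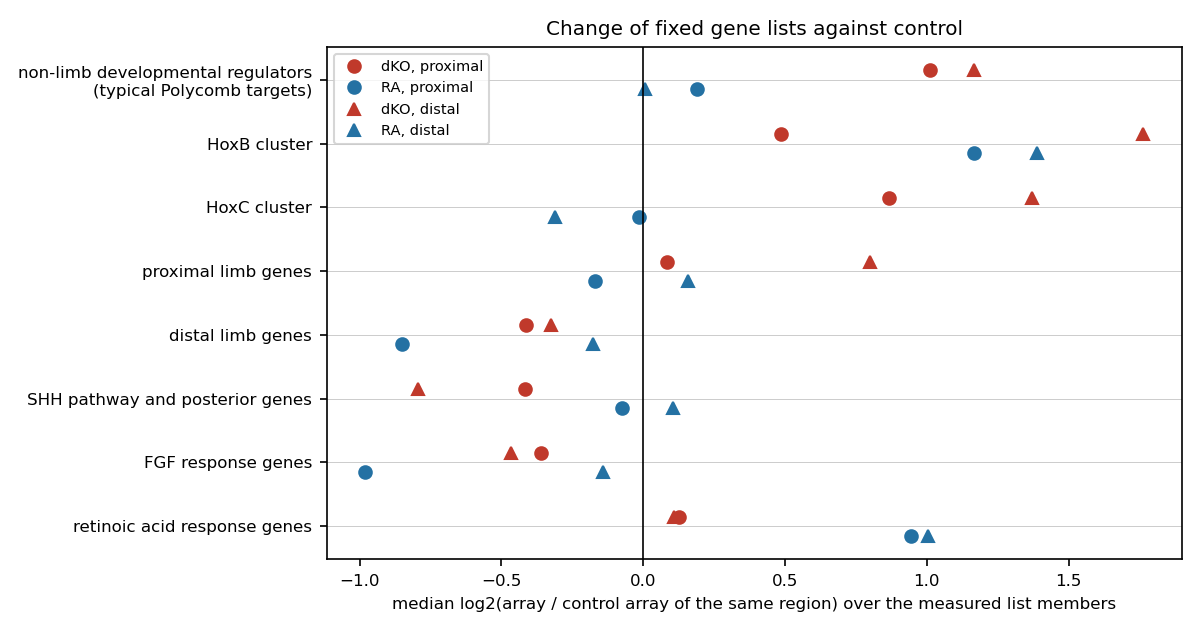
Median log2 ratio of each array to the control array of the same part for 8 gene lists; red is dKO, blue RA, circles proximal and triangles distal. The Polycomb target list lies at 1.01 and 1.17 in dKO, and the RA response list at 0.95 and 1.003 in RA.

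Genes called for position in the control pair had smaller differences in the dKO pair. The 154 genes higher proximally in control had a median difference of 1.35 there, 0.63 in dKO and 1.17 in RA, and the 159 higher distally had -1.30, -0.60 and -1.08. Against control, the former differed by a median of 1.17 in the distal and 0.31 in the proximal dKO part, and the latter by -0.32 and 0.37. Choosing genes on 1 pair favours that pair, so part of such a fall can come from the choice. Genes chosen on the dKO pair had medians of 1.22 and -1.15 there, and 0.89 and -0.93 in control. Of the lists, HoxB had a median position difference of 0.37 in dKO with 0 of 8 at 2-fold, proximal limb genes 0.22 with 0 of 10 (0.21 with 3 of 10 in the RA pair), and ridge genes -0.52 with 0 of 11. Surface ectoderm markers stayed at -0.70, with 3 of 12 lower, distal limb genes were at -0.47 against -0.33 in control, and FGF response genes at -0.41 against -0.42. Across all genes, 60 were higher proximally and 84 distally in dKO (11642 tested), of which 29 and 37 were also called in control, where independent lists would share 0.709 and 1.05. For the 1214 genes chosen on the RA pair the median was 0.11 in control and 0.26 in dKO. These genes differed little in control (0.28 for those higher proximally, 0.03 for those higher distally), so a loss could hardly show in them. With 3-fold genes the dKO value was below that of control by a log2 difference of -0.05. Dividing arrays by their median changed the dKO counts to 84 and 67, so the side with more genes turned.

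Exposure to RA is known to induce genes of RA turnover, and the comparison with control asks which transcripts differ in exposed buds. The RA response list was higher in 7 of 14 proximally and 6 of 12 distally, with 0 lower and medians of 0.95 and 1.003, above those of all 10000 random lists. Cyp26a1, an RA-degrading enzyme, rose by at least 4.30 proximally and by 5.19 distally, to signals of 1256 and 2358. Dhrs3, a retinal reductase, rose from 738 and 586 to 5251 and 4261 (2.83 and 2.86; limma adjusted p = 0.00223, SE 0.16). Rarb, an RA receptor, rose from 617 and 117 to 2814 and 2000.2 (2.19 and 4.10; limma adjusted p = 0.0488). In limma these 3 rose over all genes and 6 of 14 adjusted over the list alone. Cyp26b1 was higher by 3.46 and 1.56 and Stra6 by 1.09 and 1.03. The arrays compared also differ in Xist, Eif2s3y, BioB and the Ring1A genotype label.

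The HoxB cluster was higher in 4 of 7 proximally and 4 of 6 distally, with 0 lower and medians of 1.17 and 1.39. Hoxb3 differed by 0.97 and 2.97, Hoxb5 by 0.93 and 1.94, Hoxb4 by 1.42 and 1.41 and Hoxb6 by 1.17 and at least 1.37. In limma 0 of 8 rose over all genes and 4 were higher adjusted over the list alone. HoxA had 2 of 8 higher and 2 lower proximally and 0 distally, with 1 higher and 2 lower adjusted over the list alone. HoxC had 0 of 5 and 1 of 5 higher, Hoxc4 (1.08), and HoxD 1 of 7 lower in each part, Hoxd11 (-1.64 and -1.01). Of these, HoxC had 0 calls and HoxD 1, adjusted over the list alone. Proximal limb genes were 2-fold higher in 1 of 10 and 2 of 8 and lower in 1 each, Tbx18 (-2.66 and -1.22); Irx3 was higher distally by 1.51. Adjusted over the list alone 1 was higher and 1 lower, with 0 over all genes. Tbx2 rose by 2.48 and 1.72, the 1 call in the SHH list over all genes, beside which 1 was lower adjusted over the list alone; in that list Grem1 was lower (-2.14 and -1.32) and Shh had a distal signal of 432.5 (-1.34).

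On the proximal RA array, which stands apart in its 3'/5' ratios, its largest signals and its correlations, part of the ridge, FGF response and distal limb genes were lower. Ridge genes were lower in 4 of 8 proximally and 1 of 11 distally (medians -1.04 and -0.52), with Sp8 at -3.26 (a bound) and Sp6 at -1.59 proximally. FGF response genes were lower in 4 of 9 proximally and 0 of 9 distally, Spry4 by -1.71 and Etv5 by -1.62. Distal limb genes were higher in 1 of 14 in each part (Cyp26b1) and lower in 6 proximally and 1 distally, Sall1 by -2.37 and Lhx9 by -2.09. Limma called none of the ridge or FGF genes, and for distal limb genes 0 over all genes and 1 higher and 2 lower adjusted over the list alone. WNT pathway genes were lower in 4 of 16 and 3 of 15, Sp5 by -2.07 and -1.09 (the latter a bound) and Rspo3 by -1.91 distally; 0 fell over all genes and 4 were lower adjusted over the list alone. Smad7, an inhibitor of BMP and TGF-beta signalling, had a signal of 74.1 on the proximal RA array against 2328 in control (-4.97), and differed by 0.31 distally.

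In the other lists, somite and body wall markers had 4 higher and 3 lower of 7 proximally (median 1.11), and 1 higher and 2 lower of 6 distally (median -0.02). Foxc2 rose by 2.71 and 3.91 and Meox2 fell (-1.63 and -1.94), the 2 calls over all genes, with 2 higher and 3 lower adjusted over the list alone. Polycomb targets had 2 of 17 higher and 3 of 12 higher with 1 lower, with Wt1 higher by at least 2.70 and 1.37; 0 rose over all genes and 1 adjusted over the list alone. Surface ectoderm markers were higher in 1 of 13 (Krt15, at least 1.34) and lower in 1 proximally, and lower in 2 of 12 distally (medians -0.28 and -0.60, the latter below all random lists, beside -0.52 for the ridge genes, also ectodermal), Krt14 (-1.41) and Krt5 (-1.17) distally; 0 fell over all genes and 2 were lower adjusted over the list alone. Macrophage markers were higher in 2 of 9 distally, C1qb by 2.60 and Aif1 by at least 1.03, and none was called in limma. Limb mesenchyme genes had a distal median of -0.32, below those of all random lists, with 1 of 12 lower (Col1a1, -1.07), and 1 was lower adjusted over the list alone. Muscle markers had a distal median of -0.75, with 1 of 5 higher (Pax7, at least 1.35) and 1 lower (Lbx1, -1.52), and the Cdkn2 and p53 list one of -0.42, with 2 of 11 lower, Cdkn1a (-1.38) and Pmaip1 (-1.08). Endothelial markers had medians of 0.57 and 0.26 with 0 of 10 at 2-fold. Limma called none of these last 3 lists. After division by the array median, 4 ectoderm markers and 5 WNT genes were lower distally, and after quantile normalization 2 WNT genes proximally.

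Across all genes, 425 were higher and 783 lower proximally (11521 tested), and 246 and 243 distally (11389 tested). Both parts shared 99 higher and 110 lower genes, where independent lists would share 8.02 and 16.4. As in dKO, this overlap is not replication. Foxc2, Rarb, Prap1 (2.46 and 3.35), Dhrs3, Stk25 (2.98 and 2.52), D2hgdh (2.94 and 2.52) and Spsb1 (2.41 and 2.41) rose, and Igf1 (2.21 and 2.16), Bcl6 (1.44 and 2.91) and Cyp26b1 were higher. From the floor, besides Eif2s3y, Tmem87a rose by at least 4.05 and 4.35, Zfp874a by at least 3.21 and 2.76, Tmem132e by at least 3.61 and 2.06 and Nxph4 by at least 2.15 and 2.45. Adi1 (-3.28 and -2.54), Lats2 (-3.66 and -2.10), Mab21l2 (-2.84 and -2.10), Hspa1b (-2.59 and -1.88), Gja3 (-2.27 and -2.09) and Serhl (-2.12 and -1.79) fell, and Fat4, Ctr9, Tbx18 and Glrb were lower. Another probe set of Lats2, Ctr9, Serhl and Glrb went the other way in at least 1 part. Other probe sets of the shared genes were also counted where they changed 1.5-fold or more the same way in both parts. Of 65 for the shared lower genes 35.4% did so, against 63.0% of 54 for the shared higher genes and 74.8% of 119 in dKO. The rest include smaller changes in the same direction. To the floor, besides Xist, Prl8a2, Arntl2, Tnk1 and Sema3d were lower. The largest differences between the parts were in Pou4f1 (1.27 and -1.63), Drp2 (0.85 and -1.77), Tagln (0.39 and -1.86) and Spon1 (2.41 and 0.25) one way, and Smad7, Isg20l2 (-2.52 and 0.75), Mgat2 (-2.47 and 0.77) and Hemgn (-2.42 and 0.63) the other; these differences were not tested.

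In limma 37 genes rose and 29 fell with RA, out of 12147. Without the dKO pair 227 rose and 310 fell, again with 1 residual degree of freedom, and after quantile normalization 13 and 2. Leaving out the proximal RA array leaves 1 RA array. No disagreement of the RA effect between parts can then enter the fit, so its counts are not read as a result. Dividing each array by its median moved the median of all genes by -0.20 distally and the distal counts to 159 higher and 424 lower, 27.3% higher against 50.3%.

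In the RA pair, the question is which position differences remain. Ridge genes were lower proximally in 7 of 10 (median -1.49), distal limb genes in 7 of 14 (-1.11) and FGF response genes in 6 of 9 (-1.09), with Fgf4 at -4.51 and Sall3 at -3.73, both bounds. HoxB was higher proximally in 4 of 7 (1.91) and the anterior list in 4 of 4 (2.38), while proximal limb genes were higher in 3 of 10 with a median of 0.21 at the 74th percentile of random lists. Across all genes, 506 were higher proximally and 708 distally (11494 tested); 89 and 83 of these were also called in control, where independent lists would share 6.68 and 9.07. Genes chosen on the dKO pair had a median difference of 0.92 in control and 0.88 in RA. Those higher proximally went from 0.89 to 1.44 and those higher distally from 0.93 to 0.68, and with 3-fold genes RA exceeded control by 0.29. The side with more genes turned with the scaling: 742 and 547 after division by the array median, which moved the median of all genes by 0.12, and 629 and 577 after quantile normalization.

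The last question is whether dKO and RA share changes. In both parts and both conditions 11 genes were higher and 6 lower. Every comparison here uses the control arrays, so a control signal that deviates in both parts would move dKO and RA alike. In 1000 simulations with noise on a shared control array and the dKO and RA differences shuffled apart among genes of like signal, 6.92 genes were higher on average and at most 16, and 0.477 lower and at most 4. Without added noise the highest values were 16 and 3. The 11 higher genes therefore do not exceed what no sharing gives, while the 6 lower genes lay above all of these simulations. A control deviation common to both parts was not simulated, so it stays open for the lower genes. Pcdh8, a protocadherin, rose in dKO (2.30 proximally and at least 2.12 distally) and in RA (2.84 and at least 2.35). Cygb, a globin, rose in dKO (at least 2.20 proximally and by 1.93 distally) and in RA (at least 2.73 and by 2.996), and Prap1 and Sncaip rose under both conditions. Tmem132e was at least 2.23 and 2.06 higher in dKO, and Sdk2 1.31 and 1.25 higher in RA. Mab21l2, Gja3 and Meox2 fell under both conditions, and Rasgef1b (-2.08 and -1.35 in RA) and Hoxd11 were lower in both. Within a part, 52 higher and 18 lower genes were shared proximally and 64 and 19 distally, where independent lists would share 13.3, 2.93, 8.38 and 1.32; these comparisons use the same control array. The simulations with added noise gave means of 57.9, 9.64, 45.7 and 6.87, with highest values of 79, 20, 66 and 17. Only the 19 lower genes of the distal part lay above all of them. Without added noise the highest values were 50, 13, 43 and 8, and every count lay above. The first version holds too much noise and the second no shared control, so sharing stays undecided for the other counts. Genes higher in dKO and lower in RA numbered 11 proximally and 25 distally (26.1 and 9.79 if independent), and genes lower in dKO and higher in RA 4 and 3 (1.496 and 1.13). Across genes the dKO and RA differences correlated at r = 0.20 proximally and 0.25 distally. Simulations without any effect gave 0.50, a value that equal noise on every array fixes in advance, so it does not measure sharing. The covariance was 0.0556 and 0.0551 against a simulated 0.0219. Between opposite parts, which share no array, r was 0.081 for dKO proximal with RA distal (simulated 0.0011, covariance 0.0160) and 0.024 for dKO distal with RA proximal (simulated -0.00056, covariance 0.00737). In these, 31 higher and 8 lower genes, and 55 and 15, were shared, where independent lists would share 6.31, 0.878, 17.2 and 3.93. Shuffling among genes of like signal without added noise gave 22.2, 1.67, 40.03 and 5.30 on average and at most 36, 6, 59 and 13, so only the lower genes lay above it. With noise added as well, the highest values were 48, 11, 76 and 19, and none lay above. That noise comes on top of the noise already in the differences, so this version cannot show that sharing is absent. In opposite directions, 25 and 35 were higher in dKO and lower in RA (7.22 and 34.5 if independent), and 4 and 3 lower in dKO and higher in RA (0.767 and 1.95). For genes above the floor on all 6 arrays r was 0.031 and -0.021.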

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

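The tests of a different hybridisation, of mixed parts and of sequence variants were chosen only after the result was seen.

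In dKO, 2 genes differed 2-fold or more in opposite directions in the parts: Mup10 (-1.18 proximally and 2.36 distally) and Rcsd1 (1.14 and -1.55). In RA, 7 genes did so: Adamts4 (-1.14 and 1.484), Dhtkd1 (-1.01 and 1.004), Diras2 (at least 1.84, and -1.61 as a bound), Fam241a (-1.44 and 1.02), Hpse2 (-1.50 and 1.13), Pou4f1 (1.27 and -1.63) and Svopl (-1.74 and 1.003). They were picked out because single arrays of each part moved opposite ways, and the difference between parts was not tested. Among 2348 probe sets without a listed gene that were measured in both parts, 33 were 2-fold or more higher in dKO in both and 0 lower. Of 2594 such probe sets in RA, 169 were higher and 24 lower in both parts. Among genes measured in both parts, 333 of 11348 were higher and 21 lower in dKO, and 99 of 11087 higher and 110 lower in RA. The excess of higher probe sets without a listed gene in RA was thus not seen among genes, and its cause was not tested.

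The first pattern is the set of 209 genes 2-fold different in RA in both parts. Sex and the chromosome segment around Ring1 do not account for most of it: 2.87% of the genes were X- or Y-linked, against 3.29% of all measured genes, and among the 100 genes nearest to Ring1 the share called was 1.60 times that elsewhere, with 1.44% of the calls. The RA response genes had medians at percentile 100 of random lists in both parts, which a different hybridisation alone would not give. For the other 204 genes, a separate hybridisation or scan of the RA arrays cannot be told apart from RA, since the low BioB signal is on both RA arrays and no other. The BioC, BioD and cre spike-ins differed far less between these arrays and the others, so BioB alone marks them. Sequence variants under single probe sets may contribute and also stay open. Other probe sets changed 1.5-fold or more with the called gene in both parts 0.640 times as often in RA as in dKO. For lower genes only 35.4% did so. The Ring1A genotype and the RA exposure themselves were not separated.

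The second pattern is that the proximal RA array had 1208 genes at 2-fold against 489 on the distal one, a ratio of 2.47. A stretched signal scale would have brought the ratio near 1 after quantile normalization, where it was 2.38 (1106 against 464). Noise of dim genes would have done so among the 7315 brightest genes, where it was 6.41 (474 against 74). The array also stands apart in its 3'/5' ratios for GAPDH (1.60, others at most 1.39) and actin (1.95, others at most 1.72) and in its GAPDH 3' signal (17338, others at most 11383), signs of a difference in RNA or labelling. Such a fault, a different tissue content and a stronger RA response proximally stay open, since no test here ties any of them to the genes.

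The third pattern is the smaller position difference in dKO. Parts that mix alike in every tissue would lose all position differences alike, yet the surface ectoderm list kept 4.47 times the share that the proximal limb list kept (89.1% and 19.9%), with 40.2% for ridge genes, 37.3% for muscle markers and 145% for distal limb genes. The median of the proximal limb list is as small in the RA pair (0.21, against 0.22 in dKO and 1.10 in control), but 3 of 10 members are 2-fold higher proximally there and 0 in dKO (Irx3 1.98 and 0.79), so the list does not decide whether its loss is particular to dKO. Regression to the mean would leave the same genes equally small in the RA pair, but 69.97% of 313 genes had the larger difference there (67.0% after quantile normalization), although the RA pair spreads more widely (1214 genes at 2-fold against 313 in control), which could raise that share. Genes chosen on the dKO pair were in turn smaller in control (1.22 and -1.15 in dKO, 0.89 and -0.93 in control). The choice of genes can therefore account for part of the fall. The 1214 genes chosen on the RA pair showed no fall (0.11 in control, 0.26 in dKO), but they differed little in control. Altered position in dKO and uneven mixing of single tissues were not told apart by any test: genes higher distally in control differed by 0.37 in the proximal and -0.32 in the distal dKO part, and those higher proximally by 0.31 and 1.17.

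For the position effect, the 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes, so the 10 of 10 splits that gave at least as many say nothing about position. The highest count, 2427, came from 2 splits that, with condition kept in the fit, rest only on the difference between the proximal and the distal RA array.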

How the results depend on the processing

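Tests added only after the data were seen are those without the proximal RA array, the count over pairs without the RA pair, the exclusion of X- and Y-linked genes and the restriction to bright genes after quantile normalization. Of 785 folds of named genes under other settings and probe sets, 662 stayed within 1.5 times, 115 moved and 8 reversed; of 186 counts and medians of the comparisons, 72 stayed, 111 moved and 3 reversed. Leaving out X- and Y-linked genes gave 97 higher and 106 lower genes in RA, leaving out probe sets that can bind several transcripts left all 16 counts of genes within 1.5 times, and a fit with no trend gave 255 and 12 for dKO and 35 and 29 for RA. Signal over background limits the folds, since genes at the floor give only bounds. Unless said otherwise, the cause was not tested.

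With a floor at the 30th percentile, which admits dimmer genes, control position gave 361 and 355 genes higher and lower proximally, dKO 1103 and 103 proximally, 1292 and 123 distally and 679 and 34 in both parts. RA gave 1054 and 1044 proximally, 557 and 486 distally and 200 and 173 in both, and 41 and 41 genes held in every pair. Proximally 50.2% of the RA calls were thus higher, against 35.2% with the floor at the median. Limma called 9 lower for dKO and 21 and 6 for RA. With a floor at the 70th percentile, control position gave 44 and 40, dKO 63 and 14 proximally, 97 and 26 distally and 39 and 7 in both, RA 215 and 412 proximally, 83 and 70 distally and 30 and 28 in both, and 6 and 2 held in every pair. An offset in place of a floor gave 93 genes higher distally in control, 24 and 34 lower in dKO proximally and distally, 279 higher proximally, 112 lower distally and 51 lower in both parts in RA, and 13 and 10 in every pair.

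The mean over all probe sets gave 100 and 104 for control position, 278 and 405 higher in dKO proximally and distally and 207 in both, 247 and 379 for RA proximally, 129 lower distally, 58 lower in both, and 13 higher distally in every pair. At 3-fold, fewer genes pass by construction: 61 and 42 for control position, 153 and 11, 222 and 21 and, in both parts, 103 and 8 for dKO, 77 and 235, 85 and 53 and, in both, 32 and 21 for RA, and 6 and 4 in every pair. On genes chosen on the pair not compared, the position difference minus that of control changed sign at 3-fold, from 0.14 to -0.0499 for dKO and from -0.04 to 0.29 for RA.

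Quantile normalization gave 92 lower distally in dKO, and in limma 80 and 7 for dKO and 13 and 2 for RA. Restricted further to genes above the 70th percentile on the 4 arrays, RA gave 147 and 249 proximally and 47 and 25 distally. Division by the array median gave 68 lower proximally, 321 and 192 distally and 183 and 32 in both parts for dKO, and 159 and 424 distally for RA.

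Without any filter, limma called 324 and 444 for position, 7548 and 113 for dKO and 536 and 709 for RA; that fit includes genes at the floor on every array, whose values differ only by the floors. Without the control pair position gave 124 and 173, without the dKO pair 175 and 179 with RA at 227 and 310, and without the RA pair 205 and 226 with dKO at 1236 and 211. The proximal RA array alone left out gave 199 and 230 for position, 1225 and 210 for dKO and 468 and 703 for RA, and 246 and 243 for RA in the remaining part. That fit keeps 1 RA array, so its spread comes from the control and dKO pairs alone. It cannot test whether an RA effect is alike across parts, and its RA calls are not comparable with fits on both RA arrays. Over the control and dKO pairs, 37 genes were higher distally in both.

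The correlation of dKO with RA was 0.203 and 0.246 within a part, through the shared control array, and -0.021 for dKO distal with RA proximal among genes above the floor on all 6 arrays. Of 107 values from other probe sets of named genes, 99 kept their direction and 8 reversed: Lats2 (0.23 in distal RA), Ctr9 (0.0633 and 0.14 in proximal RA, 0.55 and 0.79 in distal RA), Serhl (0.46 in proximal RA), Glrb (0.0689 in distal RA) and Pou4f1 (-0.10 in proximal RA).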

Other observations

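The count of neighbouring genes was chosen only after the result was seen. Genes higher in dKO in both parts often lay next to each other in gene order. Of 333 such genes, 50 had a direct neighbour among them, where random draws from 11326 measured genes gave a median of 19 and at most 45 in 10000 draws; the draws were not matched on signal. Pou3f3 lay beside the noncoding gene Pantr1 (at least 2.95 proximally and 2.87 distally), Onecut2 (at least 3.07 and 3.07) beside St8sia3 (at least 3.38 and by 3.21), and the homeobox gene En2 (at least 2.15 and 2.64) beside Cnpy1 (at least 1.27 and 1.28). Hoxb13 and Hoxb9, Hoxc10, Hoxc9 and Hoxc8, Nefl and Nefm, and Foxl2 and Foxl2os were other such neighbours. Among 21 genes lower in dKO, 2 were neighbours, Saa1 and Saa2. In RA, 4 of 98 higher genes and 4 of 110 lower genes had a neighbour in the same set, where random draws gave a median of 2 and, for the higher genes, at most 12. Apart from Pou3f3, the Hox genes, Nefl, Foxl2os and Saa1, these genes were chosen after their values were seen.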
